A study of Mus musculus with 12 samples.

How the data were processed

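Splenic CD8+ T cells of C57BL/6 mice were compared between a DMSO control group (6 libraries) and a group given an EZH2 inhibitor (6 libraries), grouped by the treatment that the labels give. Per the labels' protocols, polyadenylated RNA was made into libraries with a stranded Illumina TruSeq mRNA kit and sequenced on an Illumina NextSeq as single-end reads. The deposited files hold raw read counts per gene symbol, 1 table per library, with 24421 symbols each. Per the submitters' processing notes, the tools used were FastQC 0.11.7, Trimmomatic 0.38, TopHat2 2.1.1, SAMtools 1.9 and featureCounts, with the mouse build GRCm38 (mm10). The gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that share sequence with a close relative (granzyme, class II, Psg and Klra genes), overlapping genes and antisense partners are therefore uncertain. A count of Cdkn2a adds up its 2 main products, which share exons. Library totals ran from 17215483 to 31206228 counts, and the 10 genes with the highest counts took 5.54% to 6.68% of a library.

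Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr at its default settings, which left 11727, libraries were scaled with TMM, and each gene was tested with the two-sided quasi-likelihood test of edgeR on a model with the group alone. A gene low in DMSO can pass this filter through EZH2i alone, and the reverse. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold limit was an absolute log2 fold change of at least 1. Fold changes are EZH2i against DMSO. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are counts relative to the TMM-scaled library size. For Onecut2, with 3 counts in DMSO, a ratio of summed counts with an exact 95% interval is given, which covers counting error only. Gene positions are 1-based and come from GENCODE M21 for GRCm38, in which 11304 of the tested genes and 139 of the 140 named genes were found by symbol.

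Before the data were examined, 41 gene lists were fixed, among them 12 lists of markers of other cell types, and these were tested with camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with an estimated correlation. The 33 lists with at least 3 tested members entered the adjustment. This test compares the members of a list with all other tested genes. A list called higher or lower is so relative to them, and its own median or mean can have the opposite sign. The lists were named before any value was seen, and none was chosen by the study on these libraries as far as the labels say. The genes named were fixed by rule: the 12 with the largest rise and the 12 with the largest fall among called genes with at least 2 CPM in the higher group, leaving out predicted gene models; up to 4 called members of each list by size of change, or the member with the smallest p where none was called; a fixed set that includes the PRC2 core, Cdkn loci, inhibitory receptors and cytokines; and the 3 called genes with the smallest adjusted p in each direction. Genes named outside this rule are said to be so where they appear.

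The groups share the replicate numbers 1 to 6 in the labels, which do not say what a number stands for. Deviations of same-numbered libraries from their group means correlated across genes with r of 0.213, 0.445, 0.286, 0.527, 0.317 and 0.847 for numbers 1 to 6. All 6 were over 0.1, the limit set in advance, so the numbers were taken to pair the libraries; the pairing comes from the data and not from the labels. A library correlated best with its own number for 3 of the 6 numbers. Without number 6 the lowest r was 0.0371, under the limit of 0.1, so the pairing is not settled for numbers 1 to 5. Values with the block and counts over same-numbered libraries rest on it. Values from a fit with the replicate number as a block are given where they change a call or move a count by more than 1.5 times. The replicate libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.95 in every pair, so no library was counted as a duplicate.

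The test was checked on simulated counts for this comparison, drawn for 11727 genes with the means and library sizes of the data. Without the block it recovered 30 of 67 genes changed by 1.5-fold, 52 of 67 changed by 2-fold and 63 of 66 changed by 4-fold, with 8 false calls. With the block it recovered 53 of 67, 65 of 67 and 66 of 66, with 13 false calls. The list test found the 1 list that was raised in both fits, and called 1 of 32 other lists without the block and 0 with it. The simulated genes were drawn independently of each other. In the data the estimated correlation within a list reached 0.654 (G2 and mitosis). The rate of false list calls at the preset correlation is therefore not shown by this check.

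Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no filter on low counts, a filter of at least 10 CPM in at least 6 libraries, the replicate block, and leaving out each library and each replicate number in turn. After the data were seen, thinning to equal depth, the lists and named genes without number 6, upper-quartile scaling for the share of higher calls by expression level (4 bins of tested genes by mean), the Onecut2 ratio without library 6 of either group, and the block together with an estimated correlation were added. Mitochondrially encoded genes were not analysed here, and some genes that the rule names are not reported here.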

Results

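RNA sequencing of polyadenylated transcripts was analysed in CD8+ T cells, the cytotoxic lymphocytes, taken from the spleens of C57BL/6 mice, a common inbred laboratory strain. A control group received DMSO, the solvent of the drug (n = 6 libraries), and the other group an inhibitor of EZH2 (EZH2i, n = 6 libraries). EZH2 is the enzyme of Polycomb repressive complex 2 (PRC2) that methylates lysine 27 of histone H3, a mark of repressed genes. The name, dose and duration of the inhibitor are not given in the sources used here. The DMSO libraries held 17215483 to 28092434 counts and the EZH2i libraries 19610258 to 31206228. At least 1 count was found for 13583 ± 335 genes per DMSO library and 14452 ± 174 genes per EZH2i library. The labels do not say that the 6 libraries of a group came from separate mice or cultures, so the p-values measure the spread between these libraries, which may be technical. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from the camera test; expression is given as TMM-scaled CPM, counts relative to the library total, as mean ± SD.

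The leading principal components PC1 and PC2 held 45.2% and 33.8% of the variance, and the library numbered 6 stood apart from the others in each group. On PC1, DMSO library 6 lay at -64.1 against -15.6 ± 3.93 for the other 5 DMSO libraries, and EZH2i library 6 at -23.3 against 33.1 ± 3.01 for the other 5 EZH2i libraries.

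**Figure D1:**
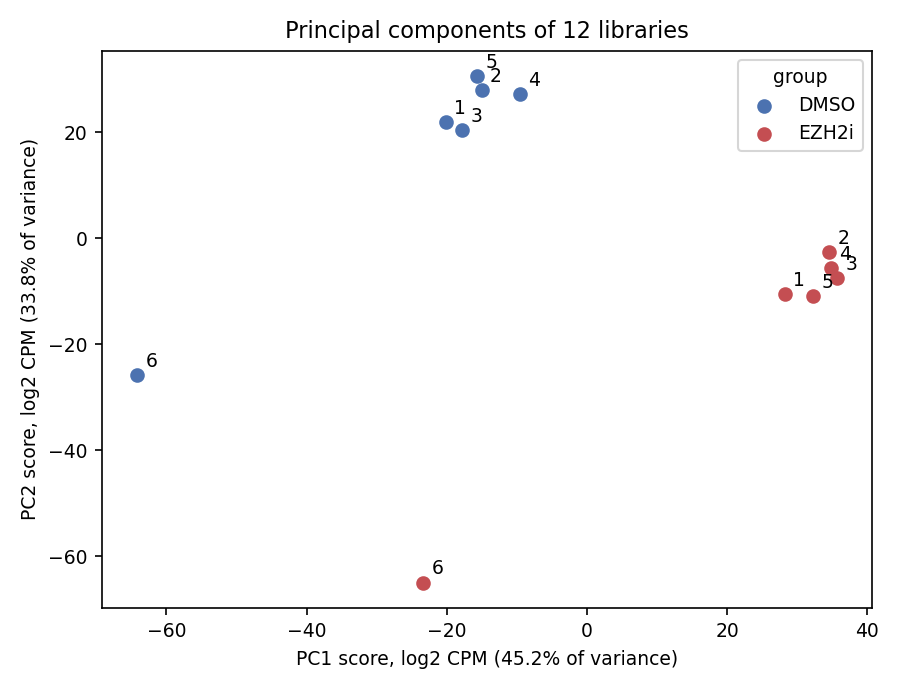
Scores of the 12 libraries on the principal components PC1 (x axis, 45.2% of variance) and PC2 (y axis, 33.8%) of log2 CPM; each point is a library, coloured by group and marked with its replicate number. Library 6 lies at -64.1 on PC1 in DMSO and at -23.3 in EZH2i, to the left of the other 5 libraries of its group.

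The comparison of EZH2i with DMSO addresses which transcripts differ when EZH2 is inhibited, in a study whose title names metabolic stress, cell death and exhaustion of lymphocytes. With EZH2i, transcripts of the cell cycle inhibitor Cdkn2a, the inhibitory receptors Pdcd1 and Tigit, the protease Gzma and the granzyme B inhibitor Serpinb9 rose, and those of DNA replication genes such as Tyms and of the surface glycoprotein Spn (CD43) fell. Of 11727 genes tested, 2266 changed, 1557 of them higher and 709 lower, against 3805 at an unadjusted p under 0.05. Changes of at least 2-fold were almost all upward, with 717 of 724 such genes higher and 7 lower. With the replicate number as a block the test called 5741 genes, 2892 higher and 2849 lower, and all 2266 genes were called in the same direction. Without both libraries numbered 6 it called 5174, 2824 higher and 2350 lower, and without EZH2i library 6 alone 4018. The share of calls that were higher was 68.7% with TMM scaling, 83.8% with upper-quartile scaling and 50.4% with the block.

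The direction of the changes differed with expression level. Tested genes were divided by mean expression into 4 bins of equal size. In the bin with the lowest expression, with mean levels of 0.404 to 8.70 CPM, 97.1% of the 905 called genes were higher, with a median log2 fold change of 1.31. In the bin with the highest expression, from 77.9 CPM, 22.8% of the 443 called genes were higher and 342 were lower, with a median log2 fold change of -0.28 among those lower. That share in the highest bin was 46.7% with upper-quartile scaling. Of all tested genes, 879 of 2932 in the lowest bin were called higher, and 342 of 2932 in the highest bin lower. The list test did not match genes on expression, so counts of called members are to be read beside these shares.

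**Figure D2:**
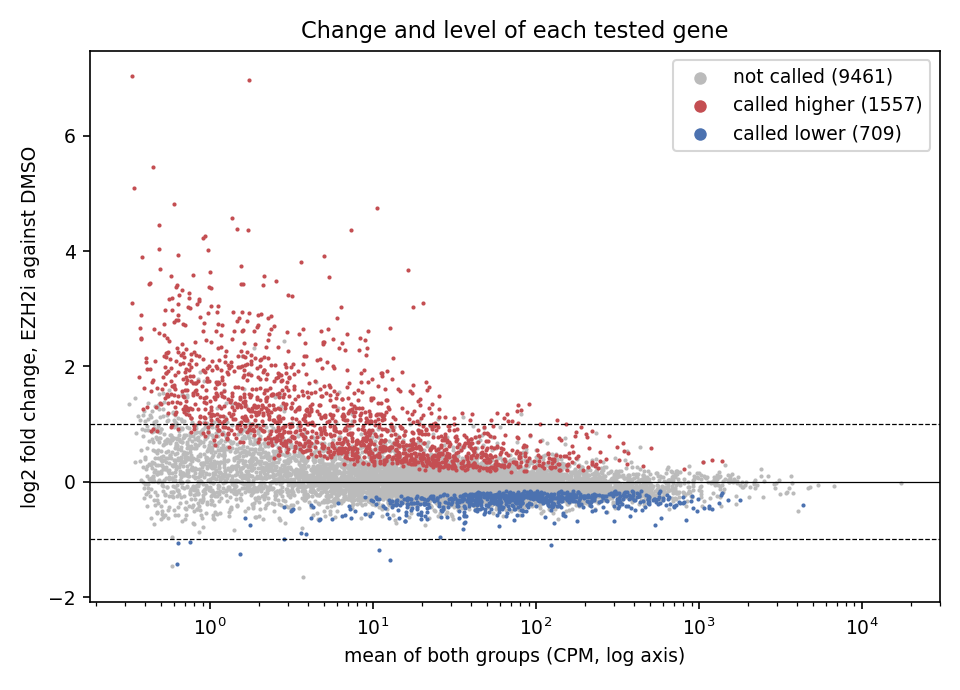
Log2 fold change of EZH2i against DMSO (y axis) against the mean CPM of both groups (x axis, log scale) for the 11727 tested genes; red and blue points are genes called higher (1557) and lower (709), grey points were not called, and dashed lines mark 2-fold. The genes changed by at least 2-fold are mostly of low expression and 717 of 724 lie above the upper dashed line.

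Ezh2 itself was measured at 278 ± 29.4 CPM in DMSO and 234 ± 26.6 CPM in EZH2i, lower in 6 of 6 same-numbered libraries, and missed the threshold (log2 fold change -0.25, SE 0.094, adjusted p = 0.0833). The adjusted p was 0.000757 with the replicate block, 0.0198 without DMSO library 6 and 0.230 with upper-quartile scaling. A small-molecule inhibitor acts on the enzyme and need not change its mRNA. Ezh2 lies on chromosome 6 from 47530139 to 47595341 in build GRCm38. The other core subunits Eed (log2 fold change -0.24, adjusted p = 0.0790, with the block 0.00214) and Suz12 (-0.18, 0.0845, with the block 0.00685), and the paralogous enzyme Ezh1 (0.30, 0.123, with the block 0.000738), missed the threshold likewise. Of 11 tested members of the PRC2 list, 1 rose, Jarid2, an accessory subunit, from 36.4 ± 2.04 to 49.0 ± 5.64 CPM (adjusted p = 0.00227). Adjusted over the list alone, 3 rose and 5 fell, as with the block over all genes. The PRC2 list was not called as a group (camera adjusted p = 0.499).

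Among the genes named by the size of their change, the rises were far larger than the falls. Igf2bp3, an RNA-binding protein of fetal tissues, rose from 2.40 ± 0.555 to 30.4 ± 3.30 CPM (log2 fold change 3.67, SE 0.15, adjusted p = 2.69e-08, higher in 6 of 6 same-numbered libraries). It lies on chromosome 6 from 49085223 to 49214957. The other large rises were Adrbk2 (4.57), Olig3 (4.38), Psg17 (4.37), Cdkn2a (4.36), Peli2 (3.91), Dlk1 (3.80), Lhfpl2 (3.73), Myrip (3.57) and Myof (3.56) on the log2 scale. Onecut2, a transcription factor of liver and nervous system, had 3 counts in all DMSO libraries together and 612 in EZH2i, a ratio of 170 (95% counting interval 58.0 to 829), with 12.2 CPM in EZH2i library 6 against 1.69 ± 0.330 in the other 5 EZH2i libraries. Its 3 DMSO counts were all in DMSO library 6. The ratio was 76.3 (95% counting interval 25.8 to 373) without EZH2i library 6, and without DMSO library 6 Onecut2 was at least 149-fold higher, taking 3 counts over the DMSO group as the floor. The transglutaminase Tgm2 rose with a log2 fold change of 4.75, from 0.788 ± 0.650 CPM, and likewise stood at 78.0 CPM in EZH2i library 6 against 8.78 ± 1.5 CPM in the other 5. Without EZH2i library 6 the log2 fold change of Tgm2 was 3.54. For Myrip it was 4.999 without DMSO library 6 and 2.89 without EZH2i library 6, and for Psg17 5.34 and 3.77. Psg17 belongs to a family of similar genes, so its count is uncertain. Nedd4, a ubiquitin ligase, rose from 45.6 ± 3.97 to 107 ± 5.92 CPM (adjusted p = 6.08e-07).

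Among called genes with at least 2 CPM in the higher group, predicted gene models left out, the strongest fall by fold change was that of Fut7, a fucosyltransferase that makes selectin ligands, from 18.2 ± 1.58 to 7.11 ± 0.808 CPM (log2 fold change -1.36, SE 0.099, adjusted p = 2.33e-06, lower in 6 of 6). Gpr34 (-1.19), Dapl1 (-1.10), Dsel (-0.998), Hemgn (-0.95), Ntrk3 (-0.91), Syt11 (-0.82), Fads2 (-0.76), Cnn2 (-0.75), Il1rl2 (-0.75), Ifi30 (-0.72) and the glutathione peroxidase Gpx1 (-0.72) followed on the log2 scale. Spn fell from 714 ± 15.8 to 463 ± 17.2 CPM (adjusted p = 3.14e-06).

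**Figure D3:**
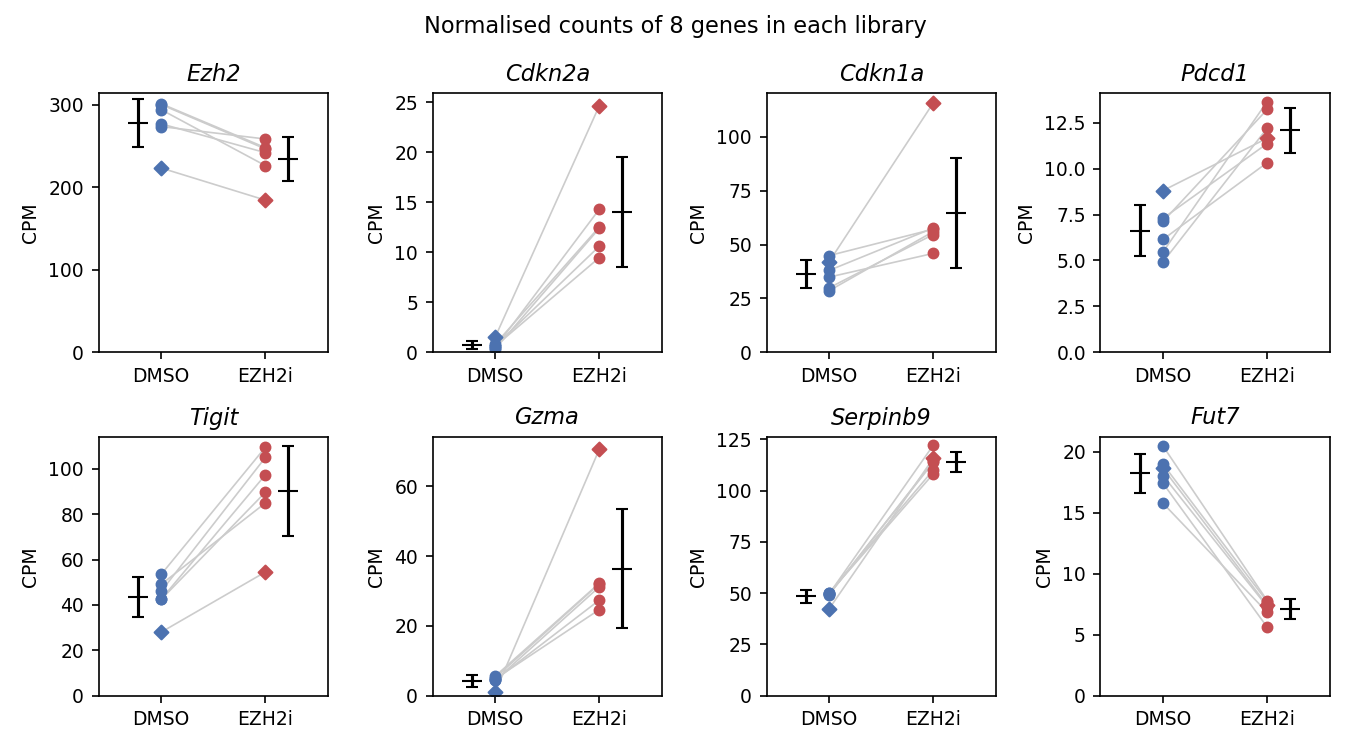
CPM (y axes, from 0) of 8 genes in each of the 6 DMSO and 6 EZH2i libraries; grey lines join libraries with the same number, diamonds mark number 6, and black bars are the mean and SD of a group. Serpinb9 rose from 48.4 to 114 CPM and Fut7 fell from 18.2 to 7.11 CPM on average, while Ezh2 missed the threshold.

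Cell cycle inhibitor loci rose as a group. Of 7 tested members 4 rose, with the same number adjusted over the list alone (camera adjusted p = 0.0266, and adjusted p = 0.150 with an estimated correlation). Cdkn2a, whose products p16 and Arf restrain cyclin-dependent kinases and Mdm2, rose from 0.702 ± 0.417 to 14.0 ± 5.48 CPM (adjusted p = 3.37e-06), and its neighbour Cdkn2b from 0.155 ± 0.176 to 1.83 ± 0.786 CPM (log2 fold change 3.63, and 4.24 without DMSO library 6; adjusted p = 0.000486). Both lie on chromosome 4, Cdkn2a from 89274471 to 89294653 and Cdkn2b from 89306299 to 89311039, and the Cdkn2a count does not separate its products. Cdkn1a (p21) rose from 36.4 ± 6.51 to 64.5 ± 25.5 CPM (adjusted p = 0.0130), and Cdkn1c (log2 fold change 1.51, adjusted p = 0.0156) also rose. Cdkn1a stood at 116 CPM in EZH2i library 6 against 54.3 ± 4.83 in the other EZH2i libraries. Its log2 fold change was 0.83, and 0.63 without number 6. Cdkn1c stood at 0.186 CPM in EZH2i library 6 against 0.941 ± 0.131 in the others, with a log2 fold change of 0.04 within number 6. The list was not called with the replicate block (camera adjusted p = 0.117).

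Target genes of p53, the tumour suppressor that answers DNA damage, were called higher as a list, with 7 of 28 tested members higher and 0 lower, and the same counts adjusted over the list alone (camera adjusted p = 0.0246). The adjusted p was 0.150 with an estimated correlation, and 14 of 100 drawn splits of the 12 libraries, the real one among them, gave an unadjusted p as small. Most of the others kept 4 or 5 of the 6 libraries of each group together. Besides Cdkn1a, Plk2 (log2 fold change 1.07), Phlda3 (0.97) and the desmosome protein Perp (0.93) rose. With the block, 11 members rose and 2 fell. Trp53, which encodes p53, had a log2 fold change of -0.25 (adjusted p = 0.153, with the block 0.00212), and Mdm2, its ubiquitin ligase and target, stood at 88.2 ± 1.27 and 89.4 ± 3.80 CPM (adjusted p = 0.819).

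Of 22 tested apoptosis regulators 3 rose and 0 fell, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.798). The members that rose were Bcl2l11 (Bim), an activator of mitochondrial apoptosis, from 154 ± 22.6 to 285 ± 35.0 CPM (adjusted p = 0.000122), the death ligand Fasl (log2 fold change 1.12) and Bik (0.73). With the block 8 rose and 5 fell. The median of the list was -0.01 and its mean 0.14, of opposite sign.

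Genes of exhaustion, the dysfunctional state of T cells under lasting stimulation, and of inhibitory receptors rose as a list. Of 19 tested members 8 rose and 0 fell, and 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00211, and adjusted p = 0.150 with an estimated correlation). Of the 32 splits of the libraries that part every same-numbered pair, 3, the real one among them, gave an unadjusted p as small. Pdcd1, which encodes the receptor PD-1, rose from 6.63 ± 1.41 to 12.1 ± 1.23 CPM (adjusted p = 0.000679), Tigit from 43.6 ± 8.71 to 90.2 ± 19.7 CPM (adjusted p = 0.000907) and Cd200r1 from 1.43 ± 0.421 to 3.14 ± 0.461 CPM (adjusted p = 0.00128). The transcription factors Tox2, with 12 counts in all DMSO libraries and 284 in EZH2i, and Tox (log2 fold change 0.49, adjusted p = 0.0157) rose. Lag3 stood at 69.9 ± 16.0 and 104 ± 23.7 CPM (adjusted p = 0.0511, with the block 1.56e-06), and Havcr2 (TIM-3), under 1 CPM in both groups, at 0.515 ± 0.397 and 0.824 ± 0.208 CPM (adjusted p = 0.278). With the block, 14 members rose and 3 fell. Mean expression of the list was lower in EZH2i library 6, at 3.88 against 4.21 ± 0.065 log2 CPM in the other EZH2i libraries. Without number 6 the list was still called higher (camera adjusted p = 0.00275, and adjusted p = 0.2295 with an estimated correlation).

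Cytotoxic effector genes rose as a list, with 5 of 14 tested members higher and 0 lower and 6 higher adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.150 with an estimated correlation). Gzma, a granule protease, rose from 4.21 ± 1.65 to 36.4 ± 17.1 CPM (log2 fold change 3.10, adjusted p = 5.82e-05), with 70.7 CPM in EZH2i library 6 and 29.5 ± 3.35 in the other 5. Serpinb9, which protects killer cells from their own granzyme B, rose from 48.4 ± 2.99 to 114 ± 4.87 CPM (adjusted p = 1.12e-07). Gzmc (1.47) and the transcription factor Zeb2 (0.87) also rose on the log2 scale. Gzmb stood at 1297 ± 611 and 1592 ± 769 CPM, with a log2 fold change of 0.30 (adjusted p = 0.567, with the block 0.00174) that was -0.01 without EZH2i library 6, 0.58 without DMSO library 6 and 0.28 without both. Granzyme genes are similar in sequence, so the split of reads between them is uncertain. With the block 8 members rose and 1 fell.

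Effector and lineage transcription factors rose as a list, with 6 of 19 tested members higher and 0 lower and 10 higher adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.150 with an estimated correlation). Prdm1 (Blimp-1), a factor of terminal effector cells, rose from 7.32 ± 0.580 to 14.6 ± 2.23 CPM (adjusted p = 4.08e-05). Maf (log2 fold change 1.94), Runx2 (0.80) and Irf8 (0.76) also rose. Tbx21 (T-bet) stood at 52.8 ± 9.19 and 50.7 ± 6.85 CPM (adjusted p = 0.788), and Id3 had a log2 fold change of -0.37 (adjusted p = 0.0967, with the block 0.00333). With the block 11 members rose and 2 fell.

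Naive and memory genes were not called as a list (camera adjusted p = 0.798), with 3 of 18 tested members higher and 0 lower, and 3 higher and 1 lower adjusted over the list alone. Eomes rose from 70.5 ± 25.5 to 140 ± 76.9 CPM (adjusted p = 0.0339), and Klf2 (log2 fold change 0.59) and Myb (0.57) also rose. Eomes stood at 119 CPM in DMSO library 6 and 294 CPM in EZH2i library 6, and its log2 fold change without number 6 was 0.86. Within number 6, Klf2 and Myb did not rise (log2 fold change -0.04 and -0.01). Tcf7, which encodes TCF-1, stood at 1411 ± 438 and 1459 ± 587 CPM (adjusted p = 0.948). Number 6 was low in Tcf7 in both groups, at 524 CPM in DMSO and 303 CPM in EZH2i. The list's median and mean were above 0 and its test, which compares members with all other tested genes, pointed lower. With the block 7 members rose and 5 fell.

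Of 11 tested cytokines and chemokines 1 rose, Ccl5 (log2 fold change 0.77, adjusted p = 0.00850), and 1 fell, Ltb (-0.52, adjusted p = 0.000118), with the same counts adjusted over the list alone and 5 higher and 2 lower with the block (camera adjusted p = 0.762). Tnf stood at 30.3 ± 14.7 and 19.9 ± 16.3 CPM (log2 fold change -0.60, and -1.18 without EZH2i library 6; adjusted p = 0.367, with the block 0.000310). Ifng, with 0.478 ± 0.197 and 0.333 ± 0.215 CPM, and Il2, with 1 count in each group, were too low to test.

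The T cell receptor complex and coreceptors fell as a list, with 5 of 16 tested members lower and 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.386 with an estimated correlation). Cd8a, by which the cells are defined, fell from 1091 ± 31.1 to 885 ± 47.3 CPM (adjusted p = 0.00129), Cd2 from 458 ± 52.3 to 302 ± 53.6 CPM (adjusted p = 0.00395) and the kinase Lck from 839 ± 64.1 to 660 ± 33.1 CPM (adjusted p = 0.00186). Cd3g (log2 fold change -0.37, adjusted p = 0.0488) also fell. With the block 9 members fell. Activation and costimulation receptors were not called (camera adjusted p = 0.770), with 2 of 20 tested members higher, Il12rb2, a receptor chain for interleukin 12, from 206 ± 14.3 to 359 ± 18.2 CPM (adjusted p = 3.14e-06), and Cd44 (log2 fold change 0.45, adjusted p = 0.0357). Adjusted over the list alone 1 was higher, and with the block 6 rose and 4 fell.

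Glycolysis was not called (camera adjusted p = 0.885), with 1 of 21 tested members higher, Pfkm, from 23.9 ± 1.82 to 33.0 ± 1.74 CPM (adjusted p = 0.000464), and 1 lower, Pdk1, from 252 ± 17.6 to 203 ± 13.2 CPM (adjusted p = 0.00446), and the same counts adjusted over the list alone. Pfkm encodes a phosphofructokinase, and Pdk1 a kinase that restrains pyruvate dehydrogenase. Hexokinase Hk2 stood at 16.8 ± 20.3 and 26.7 ± 27.8 CPM (log2 fold change 0.69, adjusted p = 0.518, with the block 2.70e-05), and the glucose transporter Slc2a1 at 64.7 ± 30.9 and 60.2 ± 16.0 CPM (adjusted p = 0.819). The log2 fold change of Hk2 was 1.66 without DMSO library 6 (adjusted p = 0.0323), -0.10 without EZH2i library 6 and 0.87 without both (adjusted p = 0.000156). The list stood higher in number 6 than in the other libraries of its group, at a mean of 7.89 against 7.08 ± 0.097 log2 CPM in DMSO and 7.65 against 7.17 ± 0.066 in EZH2i. Its median was below 0 and its mean above, and with the block 4 members rose and 5 fell.

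Mitochondrial energy genes fell as lists by small amounts. For comparison, 342 of 2932 tested genes in the highest bin of expression were called lower, and 1235 of 2932 with the block. For oxidative phosphorylation the shares were close to these, so a fall beyond that of other genes of high expression is not shown. Of the genes named below, Uqcrc1, Uqcrc2, Idh1, Cs, Acadm, Nrf1 and Hadhb lost their call with upper-quartile scaling. Of 33 tested oxidative phosphorylation genes 4 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00172, and adjusted p = 0.546 with an estimated correlation). They were Ndufa4 (log2 fold change -0.46), Ndufv1 (-0.33), Uqcrc1 (-0.29) and Uqcrc2 (-0.24), and with the block 15 fell and 1 rose. In the tricarboxylic acid cycle 5 of 21 tested members fell, and 7 adjusted over the list alone (camera adjusted p = 0.00511, and adjusted p = 0.228 with an estimated correlation), among them Idh1 (-0.49), Dld (-0.38), Pdhb (-0.29) and citrate synthase Cs (-0.20), and with the block 12 fell and 3 rose. In mitochondrial biogenesis and fatty acid oxidation 3 of 17 tested members fell, Acadm (-0.24), Nrf1 (-0.22) and Hadhb (-0.21), and 4 adjusted over the list alone (camera adjusted p = 0.0465, and adjusted p = 0.150 with an estimated correlation). The block gave 7 lower and 1 higher members of that list, which was not called (camera adjusted p = 0.0595).

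Cholesterol and fatty acid synthesis genes fell, with 6 of 26 tested members lower and 0 higher and 16 lower adjusted over the list alone (camera adjusted p = 1.58e-06, and adjusted p = 0.231 with an estimated correlation). The desaturase Scd1 fell from 30.7 ± 2.43 to 21.7 ± 1.36 CPM (adjusted p = 0.000451), and the cholesterol enzymes Cyp51 (log2 fold change -0.58) and Mvd (-0.31) and the transcription factor Srebf1 (-0.24) also fell. With the block 24 of the 26 fell.

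Amino acid transport and stress response genes were not called (camera adjusted p = 0.795), with 5 of 22 tested members higher and 1 lower, and 5 and 2 adjusted over the list alone. The mTOR inhibitor Ddit4 rose from 102 ± 19.97 to 204 ± 29.0 CPM (adjusted p = 0.000122), and Slc7a3 (log2 fold change 1.41), Slc1a4 (0.90) and Atf3 (0.79) also rose. With the block 7 rose and 7 fell. In the hypoxia response 2 of 18 tested members rose, P4ha2 (2.38, and 3.02 without DMSO library 6) and Epas1 (1.16), which encodes HIF-2 alpha, and Pdk1 fell, with the same counts adjusted over the list alone and 6 higher and 2 lower with the block (camera adjusted p = 0.567). Without number 6 the list was called higher (camera adjusted p = 0.0391, and adjusted p = 0.2295 with an estimated correlation).

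DNA replication and S phase genes fell as a list, with 15 of 26 tested members lower and 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 8.88e-09, and adjusted p = 0.150 with an estimated correlation). Tyms, the thymidylate synthase, fell from 98.7 ± 6.37 to 66.1 ± 4.09 CPM (adjusted p = 4.28e-05), Uhrf1 from 405 ± 43.5 to 303 ± 24.2 CPM (adjusted p = 0.00229), and the cyclin Ccne2 (log2 fold change -0.69) and the replication licensing factor Cdc6 (-0.43) also fell. With the block 22 fell. For G2 and mitosis the list was called lower with 1 of 25 tested members lower, Cks2 (-0.36, adjusted p = 0.000999), also adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.686 with an estimated correlation). With the block 15 of these genes fell.

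**Figure D4:**
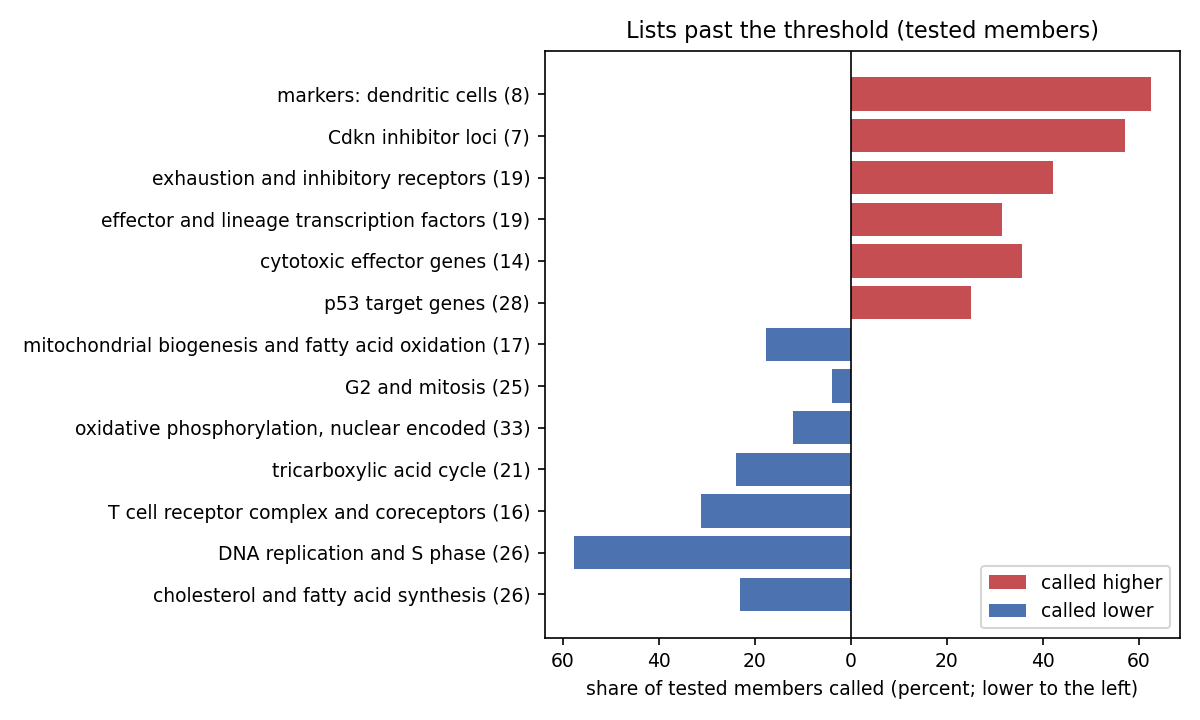
Share of tested members (x axis, percent) that were called higher (red, to the right) or lower (blue, to the left) in EZH2i for the 13 gene lists past the camera threshold, with tested members in parentheses. DNA replication and S phase has 15 of 26 members lower and exhaustion and inhibitory receptors 8 of 19 higher.

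Chromatin modifiers outside PRC2 were not called (camera adjusted p = 0.909), with 1 of 21 tested members higher and 2 lower, also adjusted over the list alone. Bmi1, a subunit of Polycomb repressive complex 1, rose from 51.0 ± 6.02 to 129 ± 10.5 CPM (log2 fold change 1.34, adjusted p = 8.39e-07), while the H3K27 demethylase Kdm6a (-0.24, adjusted p = 0.0359) and the DNA methyltransferase Dnmt1 (-0.19, adjusted p = 0.0158) fell. The list's median and mean were above 0 and its test pointed lower, and with the block 4 rose and 4 fell. Of 38 HOX and developmental regulators 2 were expressed enough to test and both rose, also adjusted over the list alone, Lhx2 from 1.85 ± 0.163 to 5.48 ± 1.02 CPM (adjusted p = 1.44e-05) and Hoxb4 (log2 fold change 1.15, adjusted p = 0.0330). Of 8 tested Wnt, BMP and Notch genes 3 rose, Bmp7 (1.29), Wnt10b (0.79) and Nrarp (0.45), also adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0546).

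Interferon-stimulated genes were not called (camera adjusted p = 0.795), with 1 of 26 tested members higher and 1 lower, Ifi27l2a (log2 fold change -0.50, adjusted p = 0.0308), and 1 higher and 0 lower adjusted over the list alone. With the block 11 rose and 7 fell. Of the 12 tested class I antigen presentation genes 0 passed the edgeR test, also adjusted over the list alone, against 4 at an unadjusted p under 0.05, 3 called by DESeq2 and 8 by limma-voom (camera adjusted p = 0.762), with Psmb8 closest (-0.22, adjusted p = 0.0534, with the block 0.00258), and 2 rose and 3 fell with the block. Of 18 tested unfolded protein and heat shock genes 2 rose, Hmox1 (1.34) and Nqo1 (0.62), both targets of the oxidative stress response, and 2 fell, Dnajb9 (-0.54) and Dnajb1 (-0.32), also adjusted over the list alone and with 7 lower with the block (camera adjusted p = 0.383). Of 49 tested cytosolic ribosomal protein genes 1 rose, Rpl13 (0.37, adjusted p = 0.0178), and 0 adjusted over the list alone (camera adjusted p = 0.770). Of 9 tested replication-dependent histone genes 0 passed the edgeR test, also adjusted over the list alone, with the block, at an unadjusted p under 0.05 or by DESeq2, and 1 was called by limma-voom (camera adjusted p = 0.795). Hist1h4d had the smallest p (-0.53, adjusted p = 0.181), and histone mRNA largely lacks the poly(A) tail by which these libraries were selected. Mitochondrially encoded mRNA was not analysed here.

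Some markers of other cell types rose. Rises were common among genes of low expression in general, with 879 of 2932 tested genes called higher in the lowest bin. Levels differed widely within the lists, with Ly6c2 at 491 ± 55.2 and 424 ± 22.4 CPM, Ctsb at 174 ± 21.8 and 168 ± 22.1 CPM and Pecam1 at 163 ± 37.9 and 146 ± 43.5 CPM in DMSO and EZH2i. In the same lists Csf1r (0.00876 and 0.0144 CPM), Adgre1 (0.0307 and 0.0181) and Dcn (0 in both groups) were near 0, with Ccr2 (22.1 and 28.2) in between. High levels of single members thus do not show that those cell types were present. These genes were named after their values were seen, as were Cd74, Cd4, Lyz2 and the dendritic cell markers that were not called. The dendritic cell list was called higher, with 5 of 8 tested members higher and 6 adjusted over the list alone (camera adjusted p = 0.000252, and adjusted p = 0.150 with an estimated correlation). These were the class II antigen presentation genes H2-Ab1, from 4.44 ± 1.0 to 15.3 ± 1.15 CPM (adjusted p = 3.14e-06), H2-Aa (log2 fold change 2.39), H2-Eb1 (2.18) and Cd74 (1.14), and the integrin Itgax (1.91). The class II genes are similar in sequence, so the split of reads between them is uncertain. Flt3 and Clec9a, which mark dendritic cells, stayed at or under 0.0372 CPM on average in both groups. Ccr9 stood at 0.551 ± 0.406 and 2.58 ± 1.37 CPM and missed the threshold (log2 fold change 2.19, adjusted p = 0.056). Zbtb46, too low to test, stood at 0.226 ± 0.116 and 0.573 ± 0.237 CPM. The remaining members were Batf3 (2.24 and 3.45 CPM, adjusted p = 0.252), Bst2 (66.65 and 66.69), Xcr1 (0.135 and 0.0589), Siglech (0.0411 and 0.0377) and Cd209a (0 in both groups). Of 9 tested NK cell markers 2 rose, Klrb1c from 0.852 ± 0.356 to 5.10 ± 2.1 CPM (adjusted p = 8.77e-05) and Itga2 (0.89), also adjusted over the list alone and with the block (camera adjusted p = 0.762). Of 5 tested mast cell markers 2 rose, the receptor Kit from 3.84 ± 0.750 to 31.4 ± 10.7 CPM (adjusted p = 1.88e-06) and Cpa3 (1.15), also adjusted over the list alone and with the block (camera adjusted p = 0.0800). Of 7 tested markers of CD4 and regulatory T cells 2 rose, Trat1 (0.64) and Zbtb7b (0.60), 3 adjusted over the list alone, with 6 higher and 1 lower with the block (camera adjusted p = 0.0764). With the block the list was called higher (camera adjusted p = 0.0306, and adjusted p = 0.272 with an estimated correlation). Cd4 itself stood at 0.0887 ± 0.0994 and 0.0984 ± 0.130 CPM.

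Of 8 tested macrophage and monocyte markers 2 rose, Hmox1 and the integrin Itgam (log2 fold change 1.28, adjusted p = 0.0112), and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.352). Lyz2, an abundant macrophage transcript, stood at 0.194 ± 0.152 and 0.283 ± 0.178 CPM. Of 3 tested stromal and endothelial markers 1 rose, Pdgfrb (2.92, adjusted p = 0.000266), and 2 adjusted over the list alone, with 2 higher and 1 lower with the block (camera adjusted p = 0.192). Of the lists with fewer than 3 tested members, the platelet list had 1 of 2 higher, the integrin Itgb3, from 130 ± 34.6 to 250 ± 62.4 CPM (adjusted p = 0.0101). No tested member passed the edgeR test in the B cell list (2 tested, Cd22 adjusted p = 0.05001, with the block 0.0113), the plasma cell list (1 tested, Sdc1 adjusted p = 0.0633, with the block 0.0274), the erythroid list (1 tested, Gata1 adjusted p = 0.119, with the block 0.0192) or the gamma-delta T cell list (1 tested, Cd163l1 adjusted p = 0.221). At an unadjusted p under 0.05 the same test gave 2, 1, 1 and 0 members of these lists in that order, DESeq2 called 2, 1, 0 and 0, and limma-voom 2, 1, 1 and 0. Adjusted over the list alone, 1 rose and 1 fell in the B cell list, 1 rose in the plasma cell and erythroid lists each, 0 in the gamma-delta list and 2 in the platelet list. None of the neutrophil markers was expressed enough to test.

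With upper-quartile scaling 15 of the named genes that fell no longer passed, with adjusted p from 0.0502 to 0.142: Cyp51, Mvd, Srebf1, Cdc6, Ifi27l2a, Acadm, Hadhb, Nrf1, Dnmt1, Kdm6a, Uqcrc1, Uqcrc2, Cd3g, Cs and Idh1. Leaving out a single library ended the call of 21 named genes in at least 1 case, with an adjusted p of at most 0.105. These were, with the number of libraries whose absence ended the call, Myb (11 of 12), Cyp51 and Cdc6 (10 each), Cd3g, Hadhb, Uqcrc1 and Wnt10b (9 each), Acadm (8), Cd44, Hoxb4 and Ifi27l2a (7 each), Eomes and Kdm6a (6 each), Cs (5) and Ccne2 (3). The remaining calls ended without EZH2i library 4 or 5 for Klf2 (highest adjusted p = 0.0511), DMSO library 1 or 2 for Uqcrc2 (0.0574), EZH2i library 5 for Epas1 (0.0515), DMSO library 5 for Idh1 (0.0598), DMSO library 2 for Il1rl2 (0.0567) and DMSO library 1 for Srebf1 (0.0557). Of the named genes that missed the threshold, Cd22 (adjusted p = 0.00167), Lag3 (0.00303), Ezh1 (0.00411), Psmb8 (0.00630), Tnf (0.00660), Id3 (0.0111), Trp53 (0.0149), Suz12 (0.0185) and Eed (0.0193) passed it without EZH2i library 6, Hk2 (0.0323) without DMSO library 6, and Sdc1 (0.0351) and Lag3 (0.0434) without DMSO library 4.

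In all, 13 of the 33 lists tested were called, 6 higher and 7 lower, and 12 with the block. With an estimated correlation 0 were called by camera, against 9 at an unadjusted p under 0.05, and 6 of 100 drawn splits of the 12 libraries, the real one among them, called at least 13 lists.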

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

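All tests in the second paragraph were chosen after number 6 had been seen to stand apart. In each group of 6 libraries the highest or lowest value was compared with the range, at a limit that chance passes in about 1 in 20 groups. Of 20 groups over 10 measures per library, 9 passed it, and 8 of these concern a library numbered 6. On PC1, DMSO library 6 lay at -64.1 against a mean of -15.6 for the others (gap of 0.808 of the range) and EZH2i library 6 at -23.3 against 33.1 (0.873). On PC2 they lay at -25.9 against 25.6 (0.820) and at -65.0 against -7.47 (0.867). Mean glycolysis expression was high in DMSO library 6 (0.782) and EZH2i library 6 (0.723), mean expression of the exhaustion list was low in EZH2i library 6, at 3.88 against 4.21 log2 CPM (0.653), and Ezh2 was low in DMSO library 6, at 224 against 289 CPM (0.645). The ribosomal RNA gene Rn45s took 0.956% of counts in DMSO library 1 against 0.367% on average in the others (0.769). Among the 140 named genes, 77 of 280 groups (27.5%) held such a library. EZH2i library 6 was the one apart for 46 genes, DMSO library 6 for 26, DMSO library 4 for 2 (Ddit4 and Hadhb), and DMSO library 5, EZH2i library 1 and EZH2i library 2 for 1 each (Il2, Il2 and Il1rl2).

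Both libraries numbered 6 differed from the rest of their group in the same way. Ribosome biogenesis genes, a list added after the data were seen, stood 1.52 (DMSO) and 1.96 (EZH2i) log2 units higher as a median, for example Srm at 152 against 23.7 ± 7.75 CPM in DMSO, while Tcf7, Il7r and Egr1 stood lower; these 4 genes were chosen after their values were seen. The tables argue against depth, since the deviations of the libraries correlated with r = 0.846 at equal depth, and against labels exchanged within the pair, since 96.2% of the genes changed 2-fold in numbers 1 to 5 went the same way in number 6. They also argue against B cells, neutrophils, erythroid cells or plasma cells in number 6, whose summed markers rose by at most 3.99 CPM. Another culture, animal or collection day, or another state of the starting cells, may account for it. The deviations correlated with r = 0.847, but the labels give no date or batch, so these cannot be told apart. Beyond the cell types above, no biological explanation was tested.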

How the results depend on the processing

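Of the settings used here, thinning to equal depth, the lists, named genes and expression bins without number 6, upper-quartile scaling for the bins, the Onecut2 ratio without library 6 of either group, and the block together with an estimated correlation were chosen after seeing the data. Where a value moved, the cause was not tested unless named. All 2266 calls were called in the same direction with the replicate block and 2261 of them without number 6, so the counts rather than the directions moved. The number of genes changed was 6232 with limma-voom, 5741 with the replicate block and 1027 with the strict filter, which tested fewer genes. Single libraries left out gave 1725 to 4018 (4018 without EZH2i library 6), and numbers left out of both groups gave 1342 to 5174 (5174 without number 6, 1506 without 1, 1416 without 2, 1389 without 3, 1342 without 5). Higher genes numbered 3191 with limma-voom, 2892 with the block, 753 with the strict filter and 1067 to 2824 with libraries left out. Lower genes numbered 347 with upper-quartile scaling, 1125 with DESeq2, 3041 with limma-voom, 2849 with the block, 274 with the strict filter and 275 to 2350 with libraries left out; they were 444, 431 and 460 without DMSO library 1, 2 or 5, 436, 438, 442 and 1788 without EZH2i library 3, 4, 5 or 6, and 338, 314 and 290 without number 1, 2 or 3 in both groups. Genes changed at least 2-fold numbered 104 with the strict filter, which removes low genes, and 623 to 840 with libraries left out. RLE scaling gave 2309 genes changed, no filter 2432 and equal depth 2180. The scalings moved the median of all genes by less than 0.1, to 0.049 with upper-quartile factors from -0.013.

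The share of calls that were higher in the lowest of 4 bins of expression was 98.2% with upper-quartile scaling, 91.7% with the block and 92.6% without number 6, and in the highest bin 46.7% with upper-quartile scaling. Ezh2 passed the threshold with DESeq2 (log2 fold change -0.261), limma-voom (-0.241), the replicate block (-0.250), without number 6 (-0.235) and without DMSO library 6 (-0.304), and single libraries left out gave -0.304 to -0.188 (without EZH2i library 6).

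With an estimated correlation 0 of the fixed lists were called by camera (9 at an unadjusted p under 0.05, and 4 with the block). The p53 list had an adjusted p of 0.0814 without a filter, 0.150 with an estimated correlation and 0.411 with that and the block; the exhaustion list had 0.150 and 0.272. Glycolysis was never called and its direction turned higher with the strict filter (adjusted p = 0.697), the block (0.985, and 0.995 with an estimated correlation), without number 6 (0.611), without DMSO library 6 (0.255) and without EZH2i library 2 (0.932), within a range of 0.255 to 0.994 over single libraries left out.

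Of the 116 named genes that were called, 116 kept their call with RLE scaling, limma-voom, the block and without number 6, 113 of 113 with a value kept it with DESeq2, and 15 lost it with upper-quartile scaling. With single libraries left out, 124 of 1392 calls were lost, in 21 genes, and 0 turned direction. Genes that were not called turned direction as follows: Slc2a1 with limma-voom (0.00223), without number 6 (0.0465) and without DMSO library 6 (0.202); Tbx21 with upper-quartile scaling (0.00498) and without DMSO library 6 (0.0228); Tcf7 with the block (-0.0574), without DMSO library 6 (-0.123) and without EZH2i library 1, 2 or 3 (-0.00772, -0.0275 and -0.0310); Gzmb (-0.0141) and Hk2 (-0.105) without EZH2i library 6. Over single libraries left out, the highest or lowest values at the other end were 0.580 for Gzmb, 1.66 for Hk2, -0.265 for Slc2a1, -0.129 for Tbx21 and 0.261 for Tcf7. Depth limits the low genes: 16593 genes had a count and 11727 passed the filter.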

Other observations

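The tests on depth, scaling, other cell types (with the marker genes they use) and imprinted genes, the counts of splits for numbers of genes, the counts over splits that part every pair and the count of neighbours without 3 family pairs were chosen after the results were seen, as were the gene pairs and imprinted genes named below. Of the called genes, Onecut2, Tox2, Kif19a, Cd63 and Speg stood under 0.1 CPM in DMSO and over 1 CPM in EZH2i, and were chosen after their values were seen. Of 27 imprinted genes, which are expressed from a single parental copy, 8 were expressed enough to test. Of these 4 rose and 0 fell, and with the replicate block 4 rose and 1 fell, Gnas (log2 fold change -0.24, adjusted p = 0.00125 with the block). Genes low in DMSO, such as Cdkn1c (0.274 CPM, against 0.815 CPM in EZH2i), can pass the filter through their EZH2i libraries. The filter may thus set part of the share that rose. The genes that rose were Dlk1, from 0.495 ± 0.291 to 6.76 ± 1.93 CPM, Cdkn1c (log2 fold change 1.51), Grb10 (1.02) and Igf2r (0.20). Rian, a noncoding RNA of the Dlk1 region, had 0 counts in every DMSO library and 0.630 ± 0.244 CPM in EZH2i. The list was called higher (camera adjusted p = 0.0194) and lost its call with an estimated correlation (adjusted p = 0.0712) and with the replicate block (camera adjusted p = 0.0654), so whether imprinted genes rise as a class stays open. Ribosome biogenesis genes had 0 of 28 called by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 22 by limma-voom, with a median log2 fold change of -0.20, and with the block 20 of them fell. That list was called lower (camera adjusted p = 0.0194, and adjusted p = 0.618 with an estimated correlation).

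Genes that rose 2-fold lay next to each other more often than in random sets matched on expression alone. There were 51 neighbouring pairs, leaving out overlapping genes and genes whose symbols share their first 3 letters, against 25 to 47 (central 95%) in 10000 random sets matched on expression (one-sided permutation p = 0.005), a test set up before its result was seen. Pairs of one family with unlike symbols were still among them, Fasl with Tnfsf4 on chromosome 1 and Bex1 with both Tceal8 and Tceal3 on chromosome X. Taking these 3 from the observed pairs alone left 48 (one-sided permutation p = 0.02). P4ha2 and Pdlim4 on chromosome 11 are an example of the others. Shared regulation of neighbouring genes may account for the excess of the 51 pairs, and further family members stay open as another source. The random sets were not matched on GC content or gene length. The number of 2-fold calls rose with both, as given below, so these stay open as well.

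Some genes of other lineages rose, among them class II genes, Kit and Klrb1c. Of the tested markers, 2 of 9 (NK) and 2 of 5 (mast cell) were called, and neither of these lists was called. In the lowest bin of expression 879 of 2932 tested genes were called higher, so such counts do not show a rise particular to these lineages. More dendritic or B cells are argued against by Cd74, abundant in them, which rose by 0.264 of the rise of H2-Ab1, to 5.23 ± 0.725 CPM. More NK cells are argued against by the summed Tyrobp, Fcer1g and Ncr1, whose change was -0.0962 of the rise of Klrb1c, and more mast cells by 6 of their abundant transcripts, which rose by 0.0501 of the rise of Kit. A change within the CD8+ T cells is a hypothesis that stays open, as do cell types outside these lists; of the markers 8 of 14 (dendritic), 9 of 14 (NK) and 5 of 9 (mast cell) were expressed enough to test, and how the CD8+ cells were isolated is not given in the sources used here.

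Changes of at least 2-fold went almost entirely upward. Deeper EZH2i libraries are argued against by libraries thinned to equal depth, where 98.9% of such calls were higher. The lowest share over TMM, RLE and upper-quartile factors was 98.7%, so the direction did not depend on the choice among them. Their medians of all genes differed little, from -0.025 (RLE) to 0.049 (upper-quartile) on the log2 scale. A shift that these scalings share could not be seen this way. Gene length and GC content are argued against as the source of the direction by a lowest share of 96.6% over 4 bins of either, with the replicate block; the number of such calls still rose with both, from 87 in the lowest bin of GC content to 331 in the highest and from 145 to 269 for length, and the median log2 fold change of all genes in the bins of GC content from -0.07 to 0.05. Loss of repression by PRC2 is a hypothesis that would give this direction, and these data hold no measure of H3K27 methylation to test it.

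Chance assignment of the libraries was examined with 100 of the 462 splits into groups of 6. For genes changed, 1 split, the real one, gave as many (2266, highest other 1375), as for genes higher (1 split; 1557, highest other 845) and genes changed 2-fold (1 split; 724, highest other 327). For genes lower, 2 splits gave as many in their larger direction (709, highest other 845). At most 2 of the 100 drawn splits, the real one among them, thus reached any of these 4 counts. Chance is not excluded by this, since the splits treat the libraries as independent. The labels do not say that they are, so a difference between cultures or animals was not tested. The other split with calls kept 5 of the 6 libraries of each group together and put both libraries numbered 6 on 1 side, so its calls may hold part of the real difference; of 44 drawn splits with both on 1 side, 43 gave 0 calls in the edgeR test. Among the 32 splits that part every same-numbered pair, 1 split gave as many without the block (2266, highest other 0) and 1 with it (5741, highest other 0). For the exhaustion list 2 of 100 splits gave a p as small (0.000320, smallest other 0.000226), but of the 32 splits that part every pair 3 did (smallest other 0.000160), and 2 with the block (0.000431, smallest other 0.000398), so chance cannot be excluded; the other splits with a p as small kept 5 of the 6 libraries of each group together. It cannot be excluded in this permutation for the number of lists called, with 6 of 100 splits (13, highest other 16), 6 of the 32 (highest other 16) and 4 of the 32 with the block (12, highest other 14). The same holds in this permutation for the p53 list, with 14 of 100 (p = 0.00819, smallest other 0.00179), 12 of the 32 (smallest other 0.000675) and 12 with the block (0.00605, smallest other 0.000541), and for glycolysis, with 93 of 100 (p = 0.858, smallest other 5.84e-06), 28 of the 32 (smallest other 2.84e-05) and 32 with the block (0.955, smallest other 5.01e-08). All these counts of splits include the real one. For the p53 list and the number of lists, most other splits that reached the real value kept 4 or 5 of the 6 libraries of each group together. They may thus hold part of the real difference.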
